A study of Mus musculus with 32 samples.

How the data were processed

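Subcutaneous white fat of 32 mice was profiled by RNA sequencing, 4 animals in each of 8 groups formed by surgery (sham or VSG) and zeitgeber time (1, 7, 13 or 19 h). Surgery, time and weight loss were taken from the labels of each sample, and replicates were numbered 1 to 4 within a group. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.2a, featureCounts 1.5.0-p1, R 3.6.3, DESeq2 1.24.0 and the genome build mm10 were used; the role of each is not given in the sources used here. The deposited signal values behave as gene counts divided by a size factor of each library: in every library 100% of the values were whole multiples of a single step within a tolerance of 0.001, which gave back whole reads. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes, and families of near-identical genes, share reads in an unknown way. The table holds 18124 genes, 15171 of them protein coding. The other deposited tables repeat these values for 17800 genes and were used only for that check.

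Recovered totals were 15.7 to 37.2 times 1e6 reads per library. The chi-square per degree of freedom between libraries of a group was 21.1 to 186 over 48 pairs, so no pair was counted as 1 sample.

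Genes with a mean of at least 10 over all libraries were kept (15588), and log2(value + 1) was fitted with limma 3.58.1 (R 4.3.3) with a mean-variance trend and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. A model with 8 group means gave the surgery effect averaged over times, the effect at each time and the interaction of surgery and time (3 degrees of freedom). A model with a 24 h cosine and sine per surgery gave rhythms and their difference, with the amplitude as the distance from mean to peak in log2 units. Within the 16 VSG libraries a slope on weight loss was fitted with a mean per time. Weight loss was compared by permuting surgery within times. Gene lists, 31 in number, were tested with camera at a preset correlation of 0.01 and with an estimated one. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

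Named genes were, for the comparison over all times, the 12 with the highest and the 12 with the lowest fold change among called genes with the same sign at all times; for each time the 3 highest and 3 lowest; for rhythms the 8 largest amplitudes; for the interaction and the rhythm difference the 8 smallest p-values; for weight loss the 5 highest and 5 lowest slopes; all core clock genes; and up to 2 called genes in each direction per list. For the groups ranked over all genes a mean of at least 50 was asked and predicted and clone names were left out. Not all of these are printed.

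Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM rescaling, quantile normalization, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered whole reads, the mean B cell and skeletal muscle lists as covariates, other designs for each comparison, and leaving out each library. Leaving out the 5 libraries high in B cell markers, the 7 high in muscle markers, or the 2 VSG animals farthest from the median weight loss was chosen after seeing the data. On whole reads edgeR called 6115 genes and DESeq2 6558 for the comparison over all times.

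The steps were tested on simulated counts drawn from the means, dispersions and depths of the 15588 genes. Each gene was drawn independently of the others and no library was made to stand apart, so recovery in the real libraries may be lower. For the comparison over all times, limma recovered 79.1% of 67 genes changed 1.5-fold, 91% of 67 changed 2-fold and 100% of 66 changed 4-fold. At a single time (ZT7) it recovered 40.3%, 59.7% and 89.4% of such genes, and for the interaction 19.4%, 43.3% and 78.8%. Rhythms of amplitude 0.5 and 1 in sham were recovered for 69% and 87% of 100 genes each, and differences in rhythm of those sizes for 48.5% and 75.5% of 200 genes each.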

Results

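RNA was sequenced from the subcutaneous white fat of mice 9 days after vertical sleeve gastrectomy (VSG), an operation that removes most of the stomach, or after a sham operation. Tissue was taken at 4 zeitgeber times (ZT, hours after lights on), ZT1, ZT7, ZT13 and ZT19, from 4 animals per surgery and time, giving 8 groups and 32 libraries, 16 per surgery. Reads assigned to genes per library, in units of 1e6, were 15.7 to 37.2, with a mean of 27.4 ± 4.72 after sham surgery and 24.8 ± 5.07 after VSG (SD, n = 16 each). Values below are the deposited normalized values, fold changes are on the log2(value + 1) scale, which understates the change of genes with low values, and 15588 genes were tested. Unless another error is named, values are means ± SD over n = 16 libraries per surgery and log2 fold changes are given ± SE, with adjusted p-values from limma.

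Animals lost more weight after VSG. The weight loss recorded for each animal, for which the labels give no unit, was 16.6 ± 3.81 after VSG (SD, n = 16) and 4.97 ± 2.03 after sham surgery (SD, n = 16). The difference of 11.6 had a two-sided permutation p of 1e-05 with surgery permuted within times in 100000 resamples, the smallest value these resamples can give.

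The first comparison asked which genes differed in subcutaneous fat between the surgeries over all 4 times. Genes of neutrophils, the phagocytes that arrive early at sites of injury, rose most. All 11 measured members of the neutrophil list rose, with a median log2 fold change of 3.605. Ngp, a granule protein gene (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012, mm10), had 508 ± 803 after VSG against 11.8 ± 25.1 after sham surgery, a 39.1-fold rise (log2 fold change 5.29 ± 0.72, adjusted p = 7.63e-06). S100a9, a calcium-binding protein abundant in neutrophils (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), rose 30.5-fold (4.93 ± 0.44, adjusted p = 1.35e-07). The granule genes Camp and Ltf rose 21.6-fold and 17.7-fold, Retnlg 18.4-fold and the chemokine receptor Cxcr2 12.2-fold. Cd177, a neutrophil surface protein gene, rose 5.84-fold, Mpo, the myeloperoxidase gene, 5.89-fold and the myeloid receptor gene Cd300lf 5.18-fold. Without the 5 libraries high in B cell markers described below, Mpo was no longer called (log2 fold change 1.21). The B cell chemoattractant Cxcl13 rose 6.80-fold and the immunoglobulin genes Ighg3 and Igkv1-110 rose 11.1-fold and 5.55-fold. Ighg3 varied widely, with 4022 ± 15042 after VSG against 38.7 ± 97.4 after sham surgery, and was not called by edgeR on whole reads (log2 fold change 3.89). Immunoglobulin genes belong to families of near-identical members, among which reads can be split, so their values are uncertain.

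The largest falls were in genes of mixed function. Pkp1, which encodes the desmosome protein plakophilin 1 (ENSMUSG00000026413, chromosome 1, 135871395 to 135919207), had 17.7 ± 25.004 after VSG against 213 ± 132 after sham surgery, a 14.5-fold fall (-3.86 ± 0.49, adjusted p = 3.82e-06). Grid1, a glutamate receptor subunit gene, fell 9.84-fold, and Tph2, which encodes a tryptophan hydroxylase of serotonin synthesis, fell 9.51-fold from 2060 ± 1320 to 218 ± 235. The carbonic anhydrase gene Car12 fell 8.61-fold, Plppr4 8.52-fold, Tekt1 7.88-fold and the proteoglycan gene Ncan 7.24-fold. The phospholipase gene Pla2g2e and the lipase gene Lipf fell 7.01-fold and 6.79-fold. Plch2, the choline transporter gene Slc5a7 and Bpifb6 fell 6.51-fold, 6.49-fold and 6.31-fold.

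In all, 6108 genes differed over the 4 times, 39.2% of the 15588 tested, with 2855 higher and 3253 lower after VSG. Of these, 511 changed by at least 2-fold (227 higher, 284 lower). A gene list with a share of called members near 39.2% does not stand apart from all genes by that count. Of the 6108, 5752 had the same sign of change at all 4 times. The fits without the 5 libraries high in B cell markers and without the 7 high in muscle markers, both chosen after seeing the data, called 5270 and 4387 genes, of which 4736 and 4209 were among the 6108 with the same direction. These fits keep 1 VSG library at ZT1 and 1 at ZT19, respectively, so a call lost in them can also come from the smaller groups.

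Most macrophage genes rose, and the inflammatory mediators were mixed. In the macrophage list 16 of 18 members rose and none fell (median log2 fold change 0.83), among them the Fc receptor gene Fcgr1 (2.58-fold, 1.37 ± 0.23) and Cd5l (2.83-fold). The call of Cd5l was lost with B cell and muscle markers as covariates (1.06) and without the 5 libraries high in B cell markers (1.01). Of 15 interferon-stimulated genes 9 rose, including Oas1a (1.57-fold) and Mx1 (1.46-fold), and 11 did when adjusted over the list alone. The call of Mx1 was lost with the same covariates (0.36) and without the 7 libraries high in muscle markers (0.60). Among 19 inflammatory mediators 9 rose (10 adjusted over the list alone), 3 fell and 7 were not called, and the list did not pass in camera (adjusted p = 0.135). The cytokine gene Il1b rose 4.64-fold (2.22 ± 0.27, adjusted p = 2.41e-06) and Lcn2 3.28-fold, while the acute-phase genes Hp and Serpina3n fell 2.48-fold and 1.87-fold. Lipid-associated macrophage genes were less uniform, with 4 of 15 higher, including Spp1 (log2 fold change 1.12 ± 0.28) and Trem2 (1.88-fold), and Ctsd lower (1.33-fold). Ctsd was not called under quantile normalization (-0.23) or without the 5 libraries high in B cell markers (-0.28).

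Many genes of lipid synthesis fell. In the cholesterol synthesis list 16 of 20 members fell and none rose (median -0.62); Nsdhl, which encodes a sterol dehydrogenase of the pathway, fell 2.14-fold (-1.10 ± 0.16, adjusted p = 1.58e-05). Of 17 genes of de novo lipogenesis 9 fell, including Acss2 (2.36-fold) and Scd2 (2.33-fold), and 2 rose, Acacb (1.84-fold) and Fads1 (1.25-fold), the latter not called without the 7 libraries high in muscle markers (0.27). Of 17 genes of fatty acid uptake and triglyceride synthesis 9 fell (10 adjusted over the list alone), led by the acyltransferase genes Mogat2 (4.57-fold) and Dgat2 (2.44-fold), and Pck1 (1.45-fold) and Slc27a1 (1.39-fold) rose. Neither was called without the 7 libraries high in muscle markers (0.65 and 0.48), and Pck1 was not called without the 5 high in B cell markers (0.28) or with the covariates (0.45). Of 21 adipocyte and adipokine genes 8 fell (9 adjusted over the list alone), among them the leptin gene Lep, with 45641 ± 21658 after VSG against 121050 ± 32161 after sham surgery (2.77-fold, -1.47 ± 0.22), and Apln (2.91-fold), and Rarres2 rose 1.19-fold (not called without the 7 libraries high in muscle markers, 0.22; 2 members rose adjusted over the list alone). The median of that list was -0.17 and turned to 0.0398 under quantile normalization.

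Many matrix and proliferation genes fell as well. Of 30 extracellular matrix genes 16 fell and none rose (median -0.62), including Col15a1 (2.29-fold) and Sparc (2.04-fold, -1.03 ± 0.14, adjusted p = 7.34e-06). Of 18 proliferation genes 14 fell (15 adjusted over the list alone) and none rose (median -0.64), among them the mitotic genes Bub1 (1.91-fold) and Ccnb1 (1.83-fold). Bub1 was not called without the 7 libraries high in muscle markers (-0.85).

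Lipolysis genes went both ways. The adrenergic receptor gene Adrb3 rose 1.73-fold, and the natriuretic peptide clearance receptor Npr3 and the lipid droplet gene Cidec fell 1.53-fold and 1.44-fold; 5 of the 15 members rose (6 adjusted over the list alone) and 5 fell. Adrb3 was not called without the 7 libraries high in muscle markers (0.60). Among 19 fatty acid oxidation genes 2 rose, including Pdk4, which encodes a pyruvate dehydrogenase kinase (1.77-fold, 0.82 ± 0.19), while 6 fell, including Etfdh (1.30-fold) and Acadl (log2 fold change -0.31 ± 0.09). Acadl was not called under quantile normalization (-0.18) or without the 7 libraries high in muscle markers (-0.30). Of 17 thermogenic genes 4 fell, led by the deiodinase gene Dio2 (4.69-fold) and Elovl3 (3.85-fold), and none rose. The mean log2 value of the thermogenic list was 7.65 in sham ZT19 replicate 4 and 7.74 in VSG ZT7 replicate 2. It was at most 6.79 in the other libraries. Of 14 fasting and FoxO targets 5 rose (6 adjusted over the list alone), including Txnip (1.51-fold), and Klf15 fell 1.38-fold, a call lost with the covariates (-0.30) and without the 5 libraries high in B cell markers (-0.40). Of 15 glucocorticoid targets 2 rose, Lcn2 and Pdk4 (3 adjusted over the list alone), and 4 fell, including Cdkn1a (1.70-fold) and Tsc22d3 (1.34-fold).

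By camera with a preset correlation, 11 of the 31 lists had an adjusted p under 0.05, 5 of them higher and 6 lower after VSG. The higher lists were neutrophil (adjusted p = 4.64e-12), macrophage (2.46e-06), interferon-stimulated genes (3.28e-04), Schwann cell and nerve (0.00829) and red blood cell (0.0467). The lower lists were cholesterol synthesis (6.25e-07), extracellular matrix (8.46e-07), proliferation (2.75e-04), fatty acid uptake and triglyceride synthesis (6.79e-04), de novo lipogenesis (0.0226) and adipocyte identity (0.0226). The correlation between members estimated for the 11 lists was 0.25 (adipocyte identity) to 0.88 (red blood cell), far above the preset 0.01. The adjusted p-values of camera with the preset are therefore likely too small. With an estimated correlation no list passed: the adjusted p was 0.419 for neutrophil, 0.583 for macrophage, interferon-stimulated genes, cholesterol synthesis, extracellular matrix and triglyceride synthesis, 0.653 for proliferation, adipocyte identity, red blood cell and Schwann cell, and 0.676 for de novo lipogenesis. Under quantile normalization 9 lists passed, without de novo lipogenesis and adipocyte identity, and with the B cell and muscle covariates 8 did, without these and the red blood cell list. Without the 5 libraries high in B cell markers 10 lists passed; the adipocyte and red blood cell lists were lost and the skeletal muscle list was gained. Without the 7 high in muscle markers 14 did, 8 higher and 6 lower, with the B cell, T cell and inflammatory mediator lists gained.

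**Figure D1:**
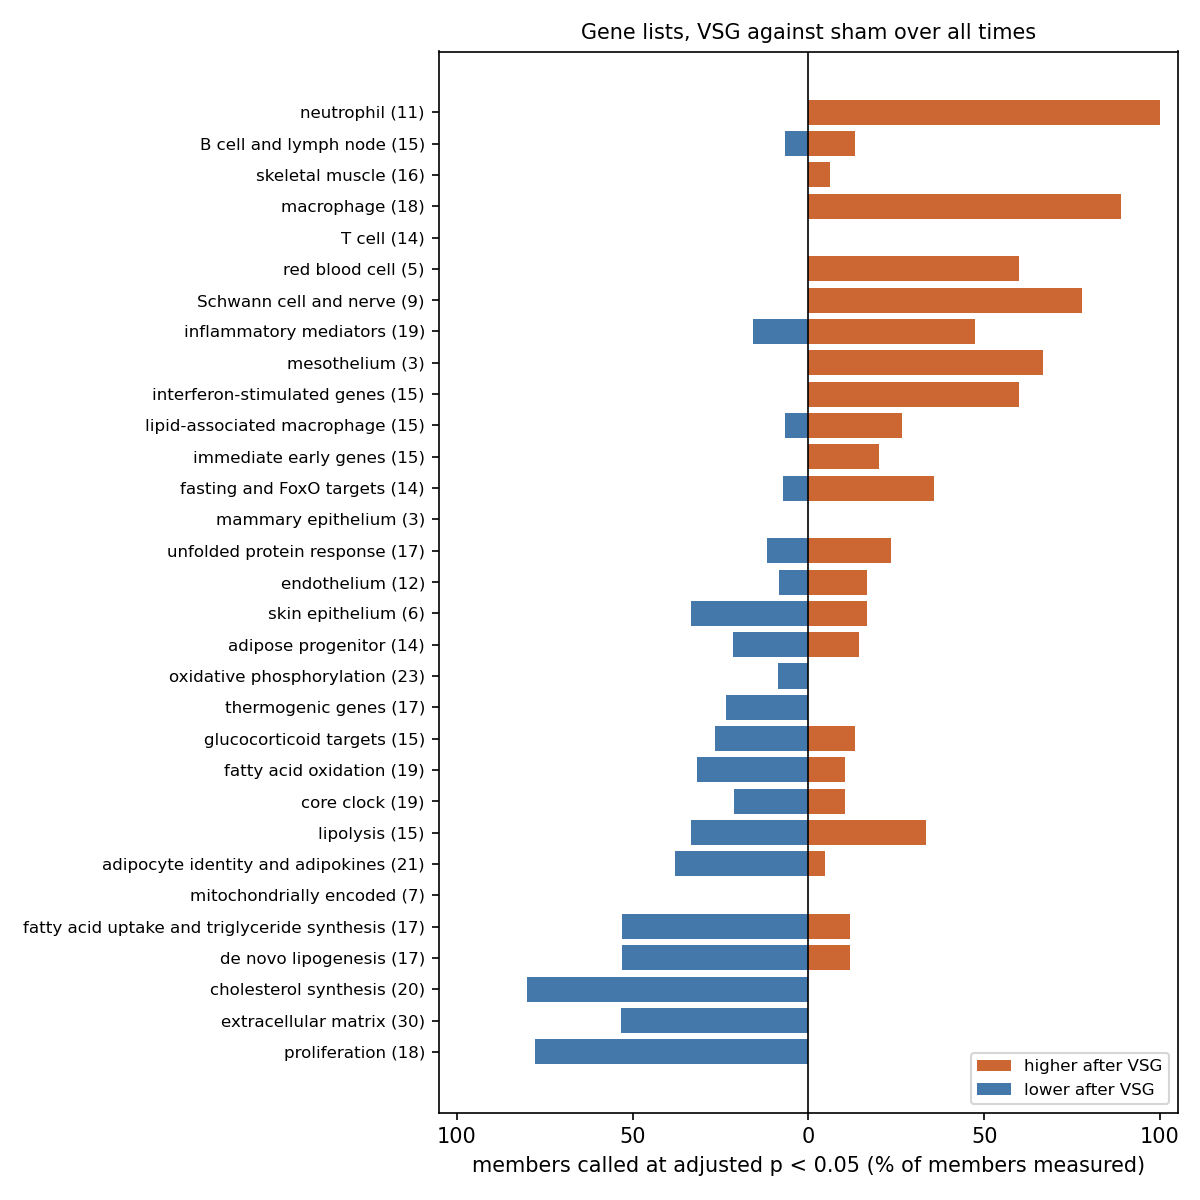
Share of the measured members of each gene list (y axis, number measured in brackets) called higher (orange, to the right) or lower (blue, to the left) after VSG over all times, in percent of members (x axis). All 11 neutrophil genes rose, and 16 of 20 cholesterol synthesis genes and 14 of 18 proliferation genes fell.

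**Figure D2:**
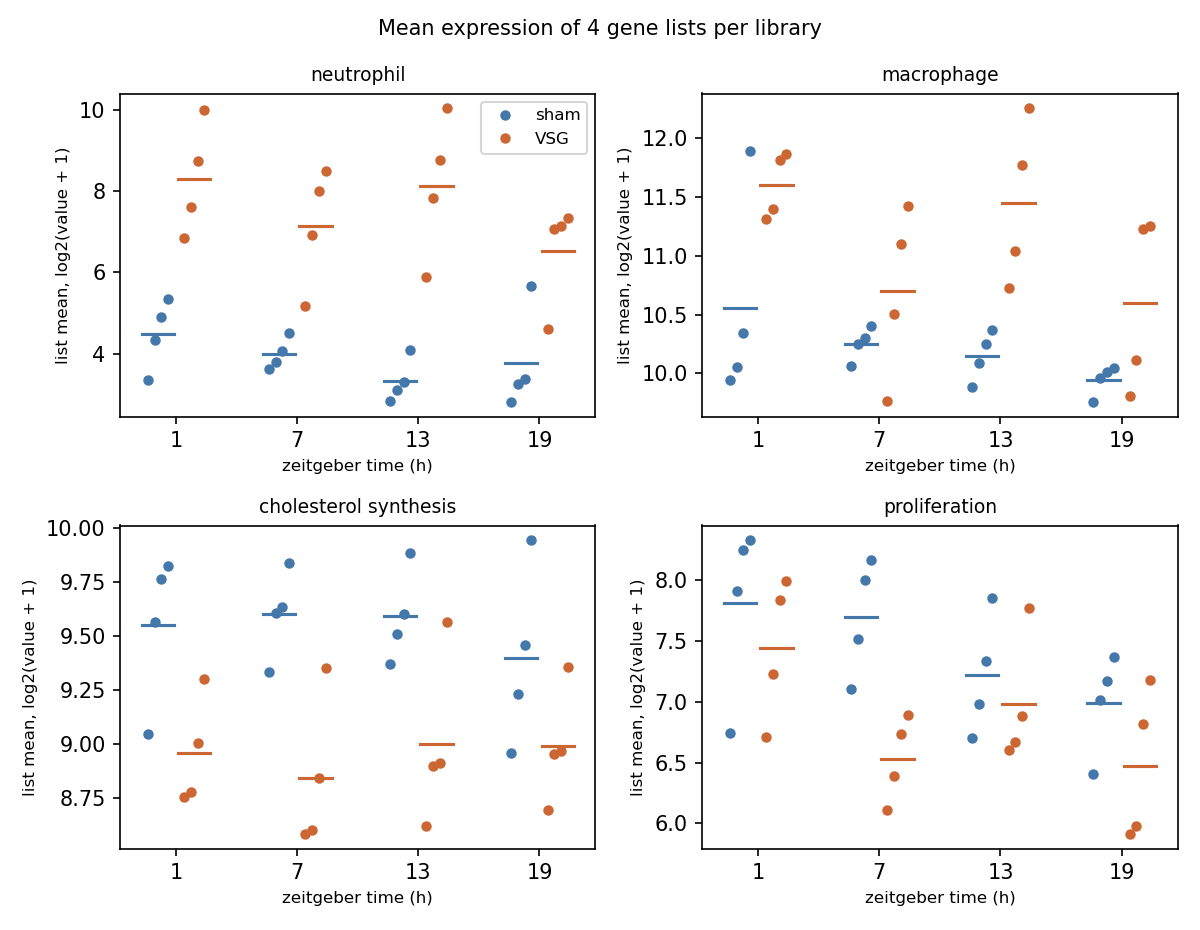
Mean log2(value + 1) of 4 gene lists (y axis) in each library (points) against zeitgeber time in hours (x axis), with the group mean as a line, sham in blue and VSG in orange, 4 libraries per group. The median log2 fold change over the list's genes was 3.605 for neutrophil, 0.83 for macrophage, -0.62 for cholesterol synthesis and -0.64 for proliferation.

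Markers of lymph node and skeletal muscle varied between libraries. The mean log2 value of the B cell and lymph node list was 8.87 or higher in 5 libraries, 1 sham and 4 VSG, and at most 7.34 in the others. The mean of the skeletal muscle list was 7.34 or higher in 7 libraries, 2 sham and 5 VSG, and at most 4.61 in the others. Of 15 B cell genes Cd22 and Cd79b rose (1 adjusted over the list alone) and Ighm, the IgM heavy chain gene, fell 3.36-fold (-1.75 ± 0.35); the list median was 1.09 (adjusted p = 0.0809 by camera). No T cell gene of 14 was called (median 0.82, adjusted p = 0.0806), and 1 of 16 muscle genes, Eno3, rose 1.80-fold (list median 0.89, adjusted p = 0.266).

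**Figure D3:**
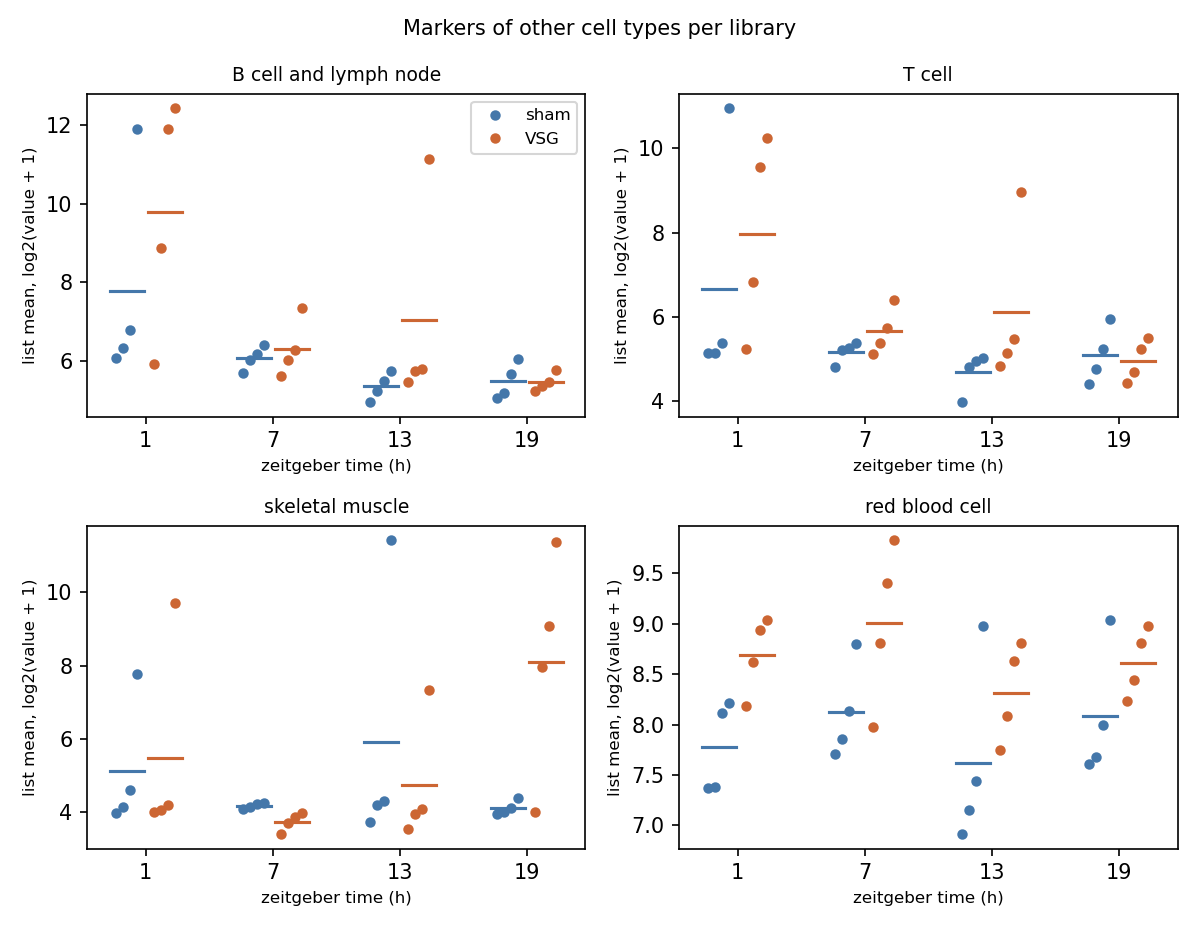
Mean log2(value + 1) of 4 lists of cell type markers (y axis) in each library (points) against zeitgeber time in hours (x axis), with group means as lines, sham in blue and VSG in orange, 4 libraries per group. Single libraries of both surgeries stand far above the rest for B cell and muscle markers, 5 libraries at 8.87 or more and 7 libraries at 7.34 or more.

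The surgeries were then compared within each time, with 4 animals per group. At ZT1 Ngp had 927 ± 1120 after VSG and 13.2 ± 16.3 after sham surgery (SD, n = 4 each; log2 fold change 6.27 ± 1.44, adjusted p = 0.0208), and Camp and Ltf rose by 5.42 ± 1.23 and 5.03 ± 1.19 on the log2 scale. Grid1 (-3.98 ± 0.90), Slc5a7 (-3.57 ± 0.80) and Pkp1 (-3.45 ± 0.97, adjusted p = 0.0376) fell most. None of these 6 genes was called from the 8 libraries of ZT1 alone, or without sham replicate 2, sham replicate 3, VSG replicate 1 or VSG replicate 3, and with the covariates Camp alone was. In all 860 genes were called, 183 higher and 677 lower. That count does not stand apart from other splits of these 8 libraries, 6 of 35 of which, the real one included, called as many or more, up to 3574 genes. Without the libraries high in B cell markers it was 3, but that fit keeps 1 VSG library at ZT1, replicate 2, itself high in muscle markers, and so does not test the 860 calls. It was 243 with the covariates, 0 from these 8 libraries alone, 1518 by DESeq2 and 3923 with array weights. It ranged from 21 without sham replicate 3 to 2873 without sham replicate 1, and was 26, 76, 44 and 1812 without sham replicate 2, VSG replicate 1, VSG replicate 3 and sham replicate 4.

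At ZT7, S100a9 had 1432 ± 1152 after VSG and 50.4 ± 15.9 after sham surgery (SD, n = 4 each; 4.29 ± 0.88), Ngp and Ltf rose by 4.80 ± 1.44 and 3.99 ± 1.19, and Pkp1 (-4.89 ± 0.97), Tph2 (-4.46 ± 1.01) and Grid1 (-4.01 ± 0.90) fell most. Pkp1 kept its call in every fit. S100a9 lost it without VSG replicate 4, Tph2 and Grid1 without several single libraries, and Ngp (adjusted p = 0.0486) and Ltf without most single libraries, with a pseudocount of 0.5 and without the filter. In all 794 genes were called, 270 higher and 524 lower. The count was 1506 with the covariates, 1269 without the libraries high in B cell markers, 1297 by DESeq2 and 4097 with array weights. Leaving out 1 library moved the count from 82, without sham replicate 1 or VSG replicate 4, to 1668, without VSG replicate 1, with 360, 107, 164 and 234 without VSG replicate 2, VSG replicate 3, sham replicate 2 and sham replicate 3.

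At ZT13 S100a9 had 2949 ± 2227 after VSG and 28.4 ± 15.2 after sham surgery (SD, n = 4 each; 6.31 ± 0.88), and Ngp and Camp rose by 6.25 ± 1.44 and 5.61 ± 1.23. Car12 (-4.30 ± 0.83), Pkp1 (-4.03 ± 0.97) and Tph2 (-3.54 ± 1.01) fell most. S100a9 kept its call in every fit. Without VSG replicate 1 Ngp, Camp, Pkp1 and Tph2 lost it, and Tph2 did so without most single libraries. Without the 7 libraries high in muscle markers S100a9 alone kept its call and the other 5 genes lost theirs. Without the 5 libraries high in B cell markers 3 of these genes lost theirs. In all 1549 genes were called, 657 higher and 892 lower. The count was 361 without the libraries high in B cell markers, which include VSG replicate 1 here, and 46 without those high in muscle markers, which include VSG replicate 3 and sham replicate 2. It was 2491 by DESeq2 and 5381 with array weights. Leaving out 1 library gave 197 without VSG replicate 1, 2759 without VSG replicate 2, 363 and 607 without VSG replicates 3 and 4, and 817, 655, 419 and 548 without sham replicates 1, 2, 3 and 4.

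At ZT19 no gene was called by limma with equal library weights, and 906 were with array weights (415 higher, 491 lower). S100a9 and Ngp had log2 fold changes of 4.51 ± 0.88 (adjusted p = 0.281) and 3.84 ± 1.44 (adjusted p = 0.660), and Pkp1 and Tph2 of -3.06 ± 0.97 and -1.68 ± 1.01. At an unadjusted p under 0.05, 1072 genes differed, edgeR called 0 genes and DESeq2 called 62. Without sham replicate 4 the limma count with equal weights was 46, and without VSG replicate 2 it was 5. Of the 4 VSG libraries at ZT19, replicates 1, 2 and 4 are high in muscle markers, so at this time muscle RNA goes with VSG.

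Whether the effect of surgery differed between times was tested by the interaction of surgery and time. No gene passed in limma (225 genes at an unadjusted p under 0.05; 0 by edgeR and 1 by DESeq2). The gene with the smallest p was Cish, an inducible inhibitor of cytokine receptor signalling, with 656 ± 714 after VSG against 184 ± 81.4 after sham surgery and an interaction adjusted p of 1.00; it was the gene called by DESeq2. The presence of calls at ZT1, ZT7 and ZT13 and their absence at ZT19 in the fit with equal weights are thus not shown to be a difference between times.

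Daily rhythms were asked of each surgery separately by fitting a cosine of 24 h. Core clock genes had the largest rhythms after sham surgery and, next to Cish, after VSG. Of 19 core clock genes 15 were rhythmic after sham surgery and 12 after VSG. Npas2, an activator partner of the clock, had an amplitude of 2.29 (log2 units) with a peak at ZT23.3 after sham surgery, and 1.94 at ZT23.1 after VSG. Arntl (Bmal1), the core activator, had 1.71 at ZT22.9 and 1.48 at ZT22.6. The repressor Nr1d1 had 1.39 at ZT7.76 and 1.46 at ZT7.54, Dbp had 1.91 at ZT10.4 and 1.85 at ZT9.56, and Per2 had 1.44 at ZT13.7 and 1.16 at ZT13.9. Ripk4 was among the 8 largest in sham (1.43), and Zbtb16 among the 8 largest in VSG (1.13). Over all times Npas2 rose (log2 fold change 0.59 ± 0.12), and Clock, Rora, Ciart and Bhlhe40 fell 1.18-fold, 1.23-fold, 1.34-fold and 1.36-fold; the fall of Bhlhe40 was lost in edgeR, in DESeq2, with the covariates, in an additive model and on leaving out many single libraries, and 3 of the list's 4 falls were called adjusted over the list alone.

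In all 250 genes were rhythmic after sham surgery and 79 after VSG, with 62 in both, where independent lists of these lengths would share 1.27. All 62 peaked within 3 h of each other, with a median absolute shift of 0.691 h, and the amplitude was larger after sham surgery in 39 of the 62. The count after sham surgery was 165 without the libraries high in muscle markers and 146, 161, 165 and 164 without sham ZT13 replicate 1, ZT7 replicate 1, ZT13 replicate 3 and ZT19 replicate 3. By DESeq2 it was 841 and with array weights 1783. The count after VSG was 207 by DESeq2, 158 with array weights, 237 by an F test between times, 46 without the libraries high in muscle markers, 27 from the 16 VSG libraries alone, 0 with a rank test and 137 without VSG ZT13 replicate 1, and 5 of 100 groupings of the VSG libraries over times, the real one included, gave as many.

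The difference in rhythm was then tested directly. Cish had the smallest p, with an amplitude of 1.99 and a peak at ZT15.0 after VSG and an amplitude of 0.18 after sham surgery (adjusted p = 0.226 in limma, not past the threshold). Enc1 (amplitudes 0.34 and 0.15 after VSG and sham surgery), Apold1 (0.49 and 0.56), Rnd1 (0.14 and 0.41) and Pbld2 (0.17 and 0.70) were also among the 8 smallest. No gene passed in limma (172 genes at an unadjusted p under 0.05; 0 by edgeR and 1, Cish, by DESeq2), so the lower number of rhythmic genes after VSG is not shown to be a loss of rhythm. Without VSG ZT19 replicate 3 the count was 1.

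**Figure D4:**
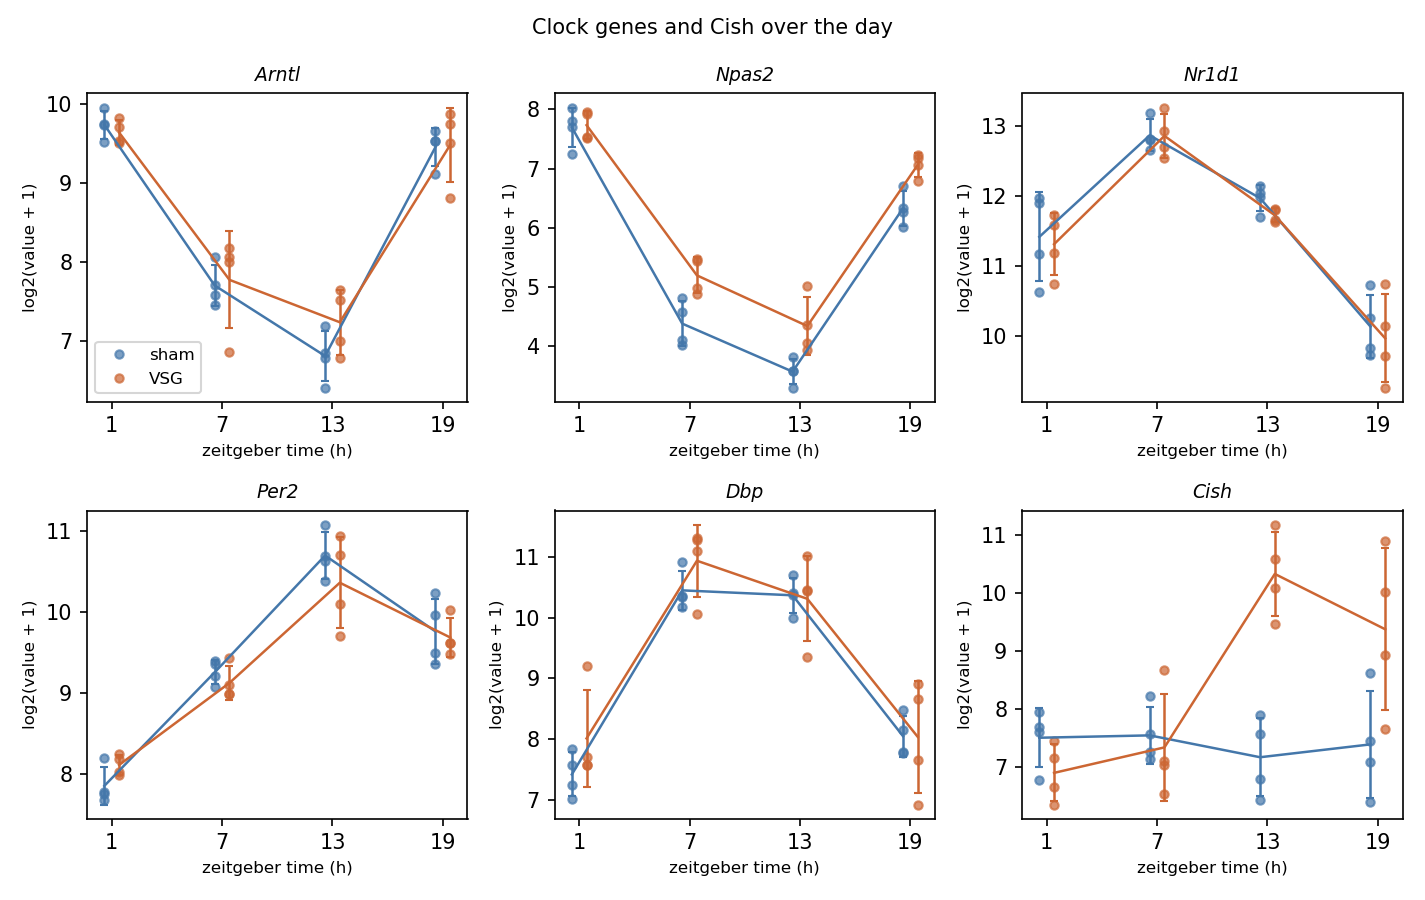
Log2(value + 1) of 5 clock genes and Cish (y axis) in each library (points) against zeitgeber time in hours (x axis), with lines through the group means and bars of 1 SD (n = 4 per group), sham in blue and VSG in orange. Npas2 was higher after VSG (log2 fold change 0.59 ± 0.12), and the fitted amplitude of Cish is 1.99 after VSG and 0.18 after sham surgery.

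Among the 16 VSG animals expression was set against weight loss, allowing for time. Of 18 macrophage genes 7 had positive slopes and 11 were not called, with no test of the list as a whole. Those 7 include Adgre1, the F4/80 gene (1.86 ± 0.42 log2 units per 10 units of weight loss, SE, n = 16). Ms4a7, outside that list, had a slope of 1.87 ± 0.40. The acute-phase gene Saa3 had the highest slope (3.81 ± 0.90, adjusted p = 0.0404), with Junb (2.24 ± 0.45) and Lipg (1.89 ± 0.47). Fasn, the fatty acid synthase gene, had the lowest slope (-2.71 ± 0.61, adjusted p = 0.0363), followed by Grid1 (-2.61 ± 0.61), Gys2 (-2.57 ± 0.60), Ncan (-2.46 ± 0.50) and Gsta3 (-2.40 ± 0.32), and 4 of 17 de novo lipogenesis and 3 of 20 cholesterol synthesis genes had negative slopes. Of 18 proliferation genes 4 had positive slopes and none a negative one, although 14 of the 18 fell after VSG. Of 423 genes called, 276 had positive and 147 negative slopes. Of the positive ones 218 were also higher after VSG (50.6 for independent lists), and 124 of the negative ones were lower (30.7). Both comparisons use the same 16 VSG libraries and genes move together, so lists expected by chance can overlap more than independent ones. The overlap therefore does not show that the surgery effect grows with weight loss. The slope calls rest on single animals, and all 10 genes named lost theirs without the 2 animals farthest from the median weight loss. The count was 0 without VSG ZT7 replicate 4, ZT13 replicate 1 or ZT19 replicate 2, 4 without ZT19 replicate 1, and 0 without the 2 animals farthest from the median weight loss (23.1 and 22.8), without the libraries high in B cell markers or without those high in muscle markers, fits that keep 12 and 11 of the 16 animals. It was 846 with the covariates, 1308 by DESeq2 and 2010 with array weights. It was 961 and 762 without ZT1 replicate 2 and ZT7 replicate 3, and 195, 152, 137, 183, 197 and 249 without ZT1 replicate 1, ZT1 replicate 4, ZT13 replicate 2, ZT13 replicate 4, ZT19 replicate 3 and ZT19 replicate 4.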

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

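The test of red blood cell markers, the test of blood of unchanged makeup, the fit without sham ZT19 replicate 4 and the use of genes shared between times or surgeries, with their direction or peak, against chance were chosen only after the result was seen.

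Of 76 groups of 4 libraries examined, 13 held a library far from the other 3. For normally distributed values chance alone flags about 1 in 20 groups. Single genes were examined without a logarithm and their values can be skewed, so this share need not hold for them. Weight loss was 8.96 in sham ZT1 replicate 4 and 2.15 to 2.63 in the other 3. The B cell list mean was 11.9 in sham ZT1 replicate 1 (others 6.07 to 6.78) and 11.1 in VSG ZT13 replicate 1 (5.46 to 5.78). The skeletal muscle list mean was 7.76 in sham ZT1 replicate 4, 11.4 in sham ZT13 replicate 2, 9.71 in VSG ZT1 replicate 2 and 7.34 in VSG ZT13 replicate 3. The neutrophil list mean was 4.60 in VSG ZT19 replicate 2 and 7.06 to 7.33 in the other 3. Pkp1 was 41.2 in VSG ZT7 replicate 1 and 101 in VSG ZT13 replicate 2, Tph2 was 553 in VSG ZT7 replicate 1, and Ngp and Camp were 17.2 and 7.24 in sham ZT13 replicate 4.

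Neutrophil genes were higher after VSG, with a median log2 fold change of 3.605 over 11 genes. All 11 were still called higher without the 5 libraries high in B cell markers, and all 11 after every library was thinned to the depth of the shallowest, which argues against lymph node RNA and depth as the cause. Red blood cell genes also rose, with a median of 0.61, past the bound of 0.5 set for it, so more blood left in the tissue may contribute. More blood of unchanged makeup is argued against as the whole cause, since the neutrophil median exceeded the red cell median by 3.00, past a bound of 1 set after the 0.61 was known. A change in the neutrophils of the blood or of the tissue after surgery stays open and was not tested.

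Of the proliferation, cholesterol synthesis and matrix lists, 46 genes were lower after VSG. With the B cell and muscle list means as covariates 97.8% of them were still called lower, and after quantile normalization 100%. These values argue against dilution by lymph node and muscle RNA and against the scaling as the cause. The surgery and the weight loss that goes with it stay open and were not tested apart. Within VSG the called slopes on weight loss were 4 positive of 18 proliferation genes, 1 positive of 30 matrix genes and 3 negative of 20 cholesterol synthesis genes. Of all genes 2.71% had a called slope. The 4 proliferation slopes run against the fall after VSG, while 1 matrix gene does not give a direction for its list. No test of these lists on weight loss was run, and these calls are lost without single animals.

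No gene was called at ZT19 by limma with equal library weights, while DESeq2 called 62 and limma with array weights 906. For each gene the within-group variance at a time was divided by its mean over the other times. The median of this ratio over genes was 0.719 at ZT19, against 1.66 at ZT1, 0.714 at ZT7 and 0.696 at ZT13. The spread at ZT19 was thus near that of ZT7 and ZT13, where genes were called, and a wider spread is argued against. The main fit uses 1 estimate of the spread per gene for all times, so the spread of a single time does not set its error there. Without sham ZT19 replicate 4 the count was 46. That library had the lowest matrix and proliferation list means of the sham libraries (12.1 and 6.40, log2). Its thermogenic, fatty acid oxidation and oxidative phosphorylation means were 7.65, 12.0 and 12.5. With those of VSG ZT7 replicate 2 (7.74, 11.8 and 12.7) they were the highest of all libraries. Leaving out 1 library gave as few as 21 at ZT1, 82 at ZT7 and 197 at ZT13, so the part of sham ZT19 replicate 4 stays open. The slope of the ZT19 change on the mean change of the other 3 times was 0.52, against 1.00, 0.93 and 1.18 for ZT1, ZT7 and ZT13, and 16 of 100 reassignments of libraries over times, the real one included, gave a slope as low, so a smaller effect at ZT19 and chance cannot be told apart. Weight loss after VSG was 14.7 ± 4.97 at ZT19 and 18.5 ± 3.01 at ZT13 (SD, n = 4 each), a difference that was not tested.

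Other splits of the libraries were counted for each comparison, the real one included. For surgery over all times 1 of 100 splits within times gave as many genes (6108, highest other 421), the smallest share that 100 splits can give. This argues against chance, though several comparisons were examined without a correction. At ZT7 and ZT13 1 of 35 splits did (794 and 1549, highest other 0 for both), the smallest share that 35 splits can give. That argues against chance but does not exclude it, since 4 times were examined without a correction. At ZT1 6 of 35 did (860, highest other 3574), so this count does not exclude chance. The ZT1 calls share 306 genes with ZT7 and 536 with ZT13, from other animals (43.8 and 85.5 for independent lists), all 306 and 536 with the same direction. The times share 1 estimate of the spread per gene and genes move together, so lists expected by chance would overlap more than independent ones. The overlap was not computed for the other splits of the ZT1 libraries, so it does not decide about chance. The splits with several times the real count point to a structure of these libraries, 4 of which are high in B cell markers. At ZT19 all 35 of 35 did (0, highest other 102). For the interaction and the rhythm difference, each gene's mean surgery effect being removed first, 100 of 100 did (0 for both, highest other 956 and 2). With a real count of 0 these 3 shares were fixed in advance and say nothing about chance. The 956 points to a structure of the libraries. For rhythms in sham 1 of 100 regroupings did (250, highest other 46). This too argues against chance, with the same limit as for surgery over all times. For rhythms in VSG 5 of 100 did (79, highest other 389), so this count does not exclude chance. Of the 79, 62 were also rhythmic in the sham animals (1.27 for independent lists), all with peaks within 3 h. This argues against chance for these 62 and leaves it open for the rest. The 2 surgeries share 1 estimate of the spread per gene in this fit, so 1.27 may be too low. For weight loss 2 of 100 reassignments did (423, highest other 589), under the bound of 5 set beforehand, though the count is 0 without some single animals.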

How the results depend on the processing

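The fits without the 5 libraries high in B cell markers, without the 7 high in muscle markers and without the 2 animals farthest from the median weight loss were chosen after seeing the data. The cause was not tested. The 6108 genes over all times became 511 at 2-fold or more and 236 with the second number of the titles as a replicate block. What that number marks is not given in the sources used here. Several of its values occur with 1 surgery only, so the block is partly confounded with surgery. The 33 same-numbered pairs gave little sign of a pairing, with a median correlation of -0.023 and 9 of them past 0.1. Of 32 libraries 5 correlated best with their own number. The block also lowers the residual degrees of freedom from 24 to 14, so the reason for the fall to 236 cannot be told. Over the other alternatives that count was 4387 to 8790, and 5488 to 6908 on leaving out 1 library.

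Array weights gave 3923, 4097, 5381 and 906 genes at ZT1, ZT7, ZT13 and ZT19, 1783 and 158 rhythmic genes in sham and VSG and 2010 for weight loss. DESeq2 gave 1518, 1297, 2491 and 62 at the 4 times, 841 and 207 rhythmic genes, 1308 for weight loss, and 1 each for the interaction and the rhythm difference. Covariates gave 243 at ZT1, 1506 at ZT7 and 846 for weight loss. Without libraries high in B cell markers the counts were 3 at ZT1 (1 VSG library left there), 1269 at ZT7, 361 at ZT13 and 0 for weight loss; without those high in muscle markers, which leaves 1 VSG library at ZT19, 46 at ZT13, 165 and 46 for rhythms in sham and VSG and 0 for weight loss; without the 2 farthest animals 0 for weight loss. The 8 libraries of ZT1 alone gave 0. Rhythms in VSG were 237 by an F test between times (all 79 among them), 0 by the rank test and 27 from the 16 libraries alone. With an estimated correlation 0 of the 31 lists passed, where 11 did before (9 under quantile normalization, 8 with covariates, 10 and 14 without libraries high in B cell and in muscle markers), and the adipocyte list median of -0.17 turned to 0.0398 under quantile normalization.

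Leaving out 1 library gave 21 to 2873 at ZT1, 82 to 1668 at ZT7, 197 to 2759 at ZT13, 0 to 46 at ZT19, 0 to 0 for the interaction, 146 to 285 and 58 to 137 for rhythms in sham and VSG, 0 to 1 for the rhythm difference, 0 to 961 for weight loss within VSG, 10 to 13 lists, and a weight loss difference of 11.2 to 12.0. Among named genes over all times, 179 of the gene and setting pairs lost the call, 12 gained one and 5229 did neither, and none reversed; 88 of the 179 came from the block. Calls of named genes were lost in 43 pairs and kept in 83 at ZT1, 29 and 97 at ZT7, 17 and 109 at ZT13, 115 and 185 for weight loss, 3 and 245 for rhythms in sham and 9 and 239 for rhythms in VSG.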

Other observations

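Some genes of other cell types also differed after VSG. Their counts are to be read beside the 39.2% of all 15588 genes called in this comparison. Of 9 Schwann cell and nerve genes 7 rose, including the myelin gene Mal (1.71-fold, 0.78 ± 0.27), not called without the 7 libraries high in muscle markers (0.62) or under quantile normalization (0.71). Of 3 mesothelium genes Lrrn4 rose 3.86-fold and Gpm6a 1.40-fold, the latter lost under quantile normalization (0.38), with the covariates (0.25), without the 5 libraries high in B cell markers (0.34) and without the 7 high in muscle markers (0.59). Of 5 red blood cell genes 3 rose, including Alas2 (1.87-fold) and Hbb-bt (1.60-fold). Of 12 endothelium genes Vwf and Pecam1 rose 1.43-fold and 1.16-fold and Kdr fell (log2 fold change -0.31 ± 0.07). Of 14 adipose progenitor genes Icam1 and Ly6a rose 1.99-fold and 1.40-fold, and 3 fell, including Zfp423 (1.46-fold). Of 6 skin epithelium genes Sfn rose 1.37-fold and Dsg1a and Krt79 fell 4.78-fold and 2.43-fold; no mammary epithelium gene of 3 was called (median 0.12).

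Of 17 unfolded protein response genes 4 rose, including Atf3 (1.68-fold) and Xbp1 (1.31-fold), and 2 fell, Dnajb9 (1.21-fold, not called without the 7 libraries high in muscle markers, -0.16) and Hspa5 (1.17-fold, not called under quantile normalization, -0.06). Of 15 immediate early genes 3 rose, including Ier3 (1.55-fold). Of 23 oxidative phosphorylation genes 2 fell, Ndufs1 (1.15-fold) and Atp5a1 (1.15-fold), neither called without the 7 libraries high in muscle markers (-0.20 and -0.22); Atp5a1 was also lost under quantile normalization (-0.04) and with the covariates (-0.15). No mitochondrially encoded gene of 7 was called (median -0.18).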
